A study of Drosophila melanogaster with 9 samples.

How the data were processed

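Total RNA from eye discs of larvae in the third instar was extracted on columns, treated with DNase, reverse transcribed and amplified by in vitro transcription to biotin-labelled cRNA, which was hybridized to the Affymetrix Drosophila Genome 2.0 Array. The 9 arrays fell into 3 groups of 3 biological replicates by their labels. The groups were control (w1118 Gal4), PSC overexpression (w1118 psc) and rbf1 mutant (rbf1120a Gal4). The Gal4 driver is not named in the labels, and the labels of the PSC group do not mention Gal4.

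The deposited values are log2 intensities per probe set that the authors made with RMA, which corrects background, normalizes between arrays and summarises the probes of each set. The RMA version is not given in the sources used here. Values ran from 2.86 to 14.85, with array medians between 5.83 and 5.92, so no further normalization was applied. The most common low value of the 11983 genes tested was 4.19. RMA compresses differences near background, and fold changes of genes that end at low values are compressed with them.

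Of 18952 probe sets, 183 control probe sets were left out. In the probe annotation used, 13647 probe sets had 1 gene, 402 had several and 4720 had none. Genes were taken from probe sets with 1 gene, and for the 1094 genes with more than 1 such probe set the set with the highest mean over all 9 arrays was kept, blind to group. This left 11983 genes. Symbols were looked up by gene identifier in a RefSeq gene table of the assembly Release 6 plus ISO1 MT, where 11894 identifiers matched and 89 did not, and no coordinates from it are given. The 402 and 4720 other probe sets entered no comparison and are described in the closing section.

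Each comparison used limma 3.58.1 in R 4.3.3. A group-means model was fitted to all 9 arrays at once, leaving 6 residual degrees of freedom per gene, with eBayes at its default settings, Benjamini-Hochberg adjustment over all 11983 genes and a threshold of 0.05. No fold minimum and no filter on dim genes were applied. The comparisons were rbf1 mutant against control, PSC overexpression against control, and rbf1 mutant against PSC overexpression, which tests the difference of both effects because both share the control arrays. Standard errors are the moderated ones from limma, with a median of 0.0753. For Rbf and Psc an exact two-sided permutation test of 3 arrays against 3 was added, whose smallest p is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

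The steps were tested on simulated data, in which 200 of 11983 genes were changed. For rbf1 mutant against control, 79.1% of genes changed by 0.5 on the log2 scale were recovered, 94.0% of those changed by 1 and 97.0% of those changed by 2, with 12 false calls. For PSC overexpression against control the shares were 70.1%, 95.5% and 100%, with 7 false calls. A simulated list shifted by 0.5 was found, and 0 of 27 unshifted lists were called. The simulated genes varied independently of each other. The list result therefore does not cover correlated genes, such as the replication list with an estimated correlation of 0.685.

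Before the data were examined, 30 gene lists were written from textbook knowledge. A member was looked up as a synonym only if none of its written names was a current symbol. They cover DNA replication and G1/S, mitosis and G2/M, cell cycle regulators with the RB/E2F/DREAM proteins, germline genes, Hox genes, other Polycomb target regulators, Polycomb and Trithorax proteins, JAK/STAT targets and ligands, Hippo pathway outputs, retinal determination, morphogenetic furrow and early neurogenesis, photoreceptor differentiation, apoptosis and stress signalling, antimicrobial peptides and immune recognition, ecdysone response, ribosome biogenesis, mitochondrial respiratory chain, heat shock, detoxification, the markers of fat body, salivary gland, muscle, haemocyte, glia, brain and neuroblast, trachea with cuticle and epidermis, other imaginal discs and antenna, genes of adult testis, male dosage compensation RNAs, and transgene and strain markers. The 28 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were run beside it. In rbf1 mutant against control 6 lists passed with the preset correlation, 0 with an estimated one (lowest adjusted p = 0.256) and 8 by fry. In PSC overexpression against control the numbers were 6, 0 (lowest adjusted p = 0.0623) and 5, and between the altered groups 5, 0 (lowest adjusted p = 0.545) and 10. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. A gene may sit in several lists. Another 4 lists (DNA repair and checkpoint, ecdysteroid synthesis in the prothoracic gland, metallothioneins and metal response, digestive enzymes and gut) were written after the largest changes had been seen, were tested apart and appear in the closing section alone.

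Named genes were chosen by a rule fixed before the data were examined. They are the altered gene, the 8 largest rises and 8 largest falls among called genes whose groups separate, the 6 largest each way with a given name, up to 4 members per list with the smallest adjusted p, and all members of lists of 5 or fewer. Between the altered groups the 4 largest each way were taken, and among genes called in both comparisons the 4 largest per direction class. Where a count was 5 or fewer, further members were named after their values were seen, as were single members picked to illustrate a larger count. Members of the 4 later lists were likewise named after their values were seen.

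Because both comparisons share the control arrays, their overlap was set beside 50 simulations of unchanged groups against shared controls and beside the overlap of independent lists. Alternatives were median centring, a further quantile normalization, a fit of only the 6 arrays compared, the replicate number as a block, eBayes with trend and robust options, array weights, the mean of all probe sets per gene, every probe set, genes above the median level only, a 2-fold minimum, a threshold of 0.01, an unmoderated test and each array left out in turn. A covariate made of the mean of 6 glue genes per array was added after the data were seen, as were lists without Rbf and Psc.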

Results

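RNA from eye imaginal discs of Drosophila melanogaster larvae in the third instar was measured on 9 arrays. The eye disc is the larval epithelium that forms the adult eye. The arrays fell into 3 groups of 3 biological replicates. The control discs carried w1118 with Gal4, the rbf1 mutant discs carried rbf1120a with Gal4, and the remaining discs overexpressed PSC. Rbf is the fly retinoblastoma family protein that binds E2F at cell cycle genes, and PSC (Posterior sex combs) is a subunit of Polycomb repressive complex 1. The question named for the series is how the rbf1 mutation and PSC overexpression each affect expression in this tissue relative to control discs. Values are log2 intensities, and their medians per array lay between 5.83 and 5.92. Pearson correlations across genes ran from 0.986 to 0.996 between arrays of one group and from 0.980 to 0.994 between groups. The first principal component held 35% of the variance and the second held 18.9%. The groups overlapped on the first, at -8.83 to 34.91 in control, -13.55 to 12.86 in PSC and -28.37 to -5.06 in rbf1 arrays. On the second, rbf1 arrays (0.64 to 21.22) lay above PSC arrays (-19.93 to -1.01), and both overlapped control arrays (-13.70 to 3.35). There were 3 arrays per group, and their number limits the precision. Stock goes with the group, so a change in 1 altered group cannot be told apart from a difference between stocks. Arrays are named below by group and replicate number, as in control 1.

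The 2 altered genes were read first. Psc (probe set 1631095_at) was 12.50 ± 0.02 (SD, n = 3) in PSC overexpressing discs and 9.84 ± 0.03 in control discs, a rise of 2.67 on the log2 scale (SE 0.058), or 6.35-fold, with a limma adjusted p of 3.12e-07. In rbf1 mutant discs Psc was 9.97 ± 0.11, a difference of 0.14 that did not pass (limma adjusted p = 0.1995). Rbf (probe set 1623479_at) was 9.42 ± 0.10 (SD, n = 3) in rbf1 mutant discs and 9.78 ± 0.10 in control discs. It fell by 0.37 (SE 0.096, limma adjusted p = 0.0479). In PSC discs Rbf was 9.80 ± 0.17, a difference of 0.020 (limma adjusted p = 0.943). For both genes, the exact two-sided permutation test of the altered group against control gave p = 0.1, the smallest that 3 arrays against 3 allow. The Rbf call was lost without control 1 (adjusted p = 0.133), control 2 (0.132), rbf1 1 (0.116), rbf1 2 (0.0710) or rbf1 3 (0.145), with log2 fold changes between -0.42 and -0.31. It was also lost with the mean of 6 salivary glue genes as a covariate, chosen after the data were seen (adjusted p = 0.0970). Which part of the Rbf transcript the probe set reads was not analysed here.

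**Figure D1:**
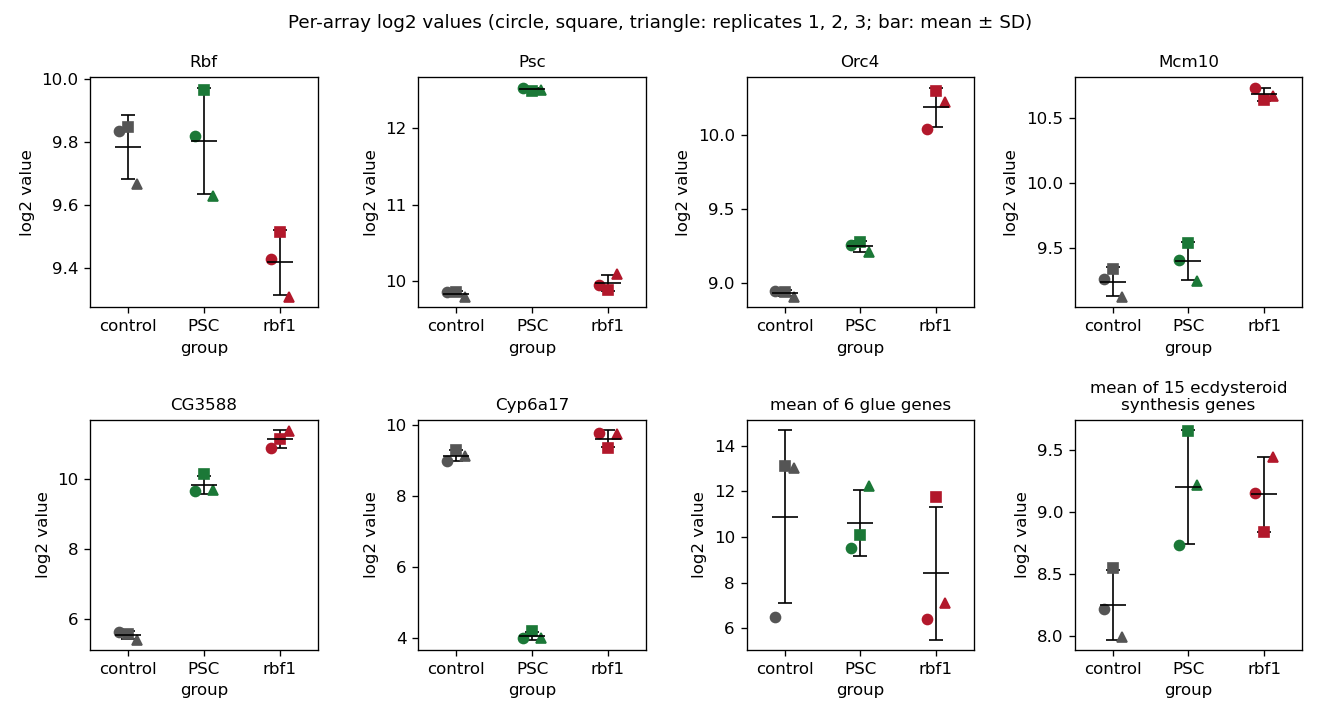
Log2 value of each array (circle, square and triangle for replicates 1, 2 and 3) by group for Rbf, Psc, Orc4, Mcm10, CG3588 and Cyp6a17 and for the means of 6 glue genes and of 15 ecdysteroid synthesis genes, with bars at the mean ± SD (n = 3). Psc stands at 12.50 in the PSC group against 9.84 in the control, and the glue gene mean runs from 6.52 to 13.10 within the control group.

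In rbf1 mutant discs the genes of DNA replication rose together against control. Of the 43 measured members of the replication and G1/S list, 40 rose and 0 fell, and the median member was 2.28-fold higher. Orc4, a subunit of the origin recognition complex, rose by 1.26 (SE 0.067) from 8.93 ± 0.02 to 10.19 ± 0.13 (SD, n = 3). Mcm10, which acts at replication initiation, rose by 1.44 (SE 0.083) from 9.24 ± 0.11 to 10.68 ± 0.05, and PolE1, the catalytic subunit of DNA polymerase epsilon, rose by 1.45 (SE 0.086). The largest single rise was that of CG3588, by 5.59 (SE 0.158), and the largest fall was that of inaE, a diacylglycerol lipase gene that acts in phototransduction, which was 15.9-fold lower (SE 0.087 on the log2 scale). Each rests on 1 probe set, the brightest of its gene. The other CG3588 probe set stood at 0.34 and the other 4 of inaE between -0.61 and 0.12, and with the mean of all probe sets the changes were 2.96 and -0.96.

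Across the 11983 genes tested with limma, 1226 passed an adjusted p of 0.05 in rbf1 mutant against control, 756 higher and 470 lower. Of these, 110 were at least 2-fold higher and 54 at least 2-fold lower, and 2790 genes had an unadjusted p under 0.05. The 3 values of one group lay entirely above those of the other for 28.9% of genes, where chance gives 10%. With arrays centred on their medians the split was 559 higher and 603 lower, where without centring 61.7% of the calls were higher. Without rbf1 2 the count was 787, and with an unmoderated test of only the arrays compared it was 481.

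Among the largest rises, after CG3588 (48.0-fold, adjusted p = 9.21e-07 from limma), were CG14419 by 3.69 (SE 0.369), the sugar transporter gene sut2 by 3.18 (SE 0.193) and UK114 by 2.66 (SE 0.090). CG18473 rose by 2.45, CG11893 by 2.20, the cap-binding initiation factor gene eIF4E3 by 2.13, pst by 2.08, the sugar taste receptor gene Gr64a by 1.90 and the maltase gene Mal-B1 by 1.83. inaE (limma adjusted p = 1.68e-07) reached 3.86 ± 0.16 (SD, n = 3) in the mutant, below the most common low value of the genes tested, 4.19. Falls followed in CG13032 at -3.48 (SE 0.141), CG8850 at -3.01 (SE 0.106), CG34296 at -2.93 (SE 0.367) and Hsc70-2, of the Hsp70 family, at -2.86 (SE 0.226). CG3097, CG6034 and CG5096 fell, at -2.40, -2.39 and -2.17. The metallothionein gene MtnB fell by 2.12, with the ubiquitin ligase gene Rnf11 at -1.94, the maltase gene Mal-A1 at -1.93 and the odorant binding protein gene Obp99b at -1.68. In PSC discs the brightest Rnf11 probe set, used here, stood at -0.71 and did not pass. The other Rnf11 probe set stood at -1.94 in the rbf1 mutant and -2.16 in PSC discs, and passed in both. The fall of Rnf11 is therefore not shown to be particular to the rbf1 mutant. Obp99b lost its call without control 1, control 3, rbf1 1 or rbf1 2, with limma adjusted p up to 0.0884.

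As lists, cell cycle genes beyond replication moved less. Of the replication list, 41 members rose adjusted over the list alone, and its median was 1.19 (quartiles 0.84 and 1.35). The histone chaperone gene asf1 rose by 1.09 (SE 0.059). Psf2 at 0.19, chif at 0.087 and Psf1 at -0.020 did not pass. The camera test in limma gave adjusted p = 5.2e-47 with a preset correlation, and adjusted p = 0.256 with an estimated correlation. Of the 41 measured mitosis and G2/M genes, 20 rose and 0 fell (25 and 1 adjusted over the list alone), with a median of 0.26. The Cdc25 phosphatase gene twe rose by 1.54 (SE 0.102), the centromeric histone gene cid by 1.35 (SE 0.124), the condensin gene glu by 0.92 (SE 0.076) and the separase subunit gene thr by 0.78 (SE 0.078). For mitosis genes adjusted p was 1.79e-11 by camera in limma, and adjusted p = 0.642 with an estimated correlation. Without rbf1 2, 12 of its members rose. Of 17 RB, E2F and DREAM proteins and cell cycle regulators, 6 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.12. They were lin-52 at 0.72, Cdk2 at 0.95, Rbf2 at 0.94, Dp, the partner of E2F, at 0.42, mip120 at 0.43 and Caf1-55 at 0.40, and the member that fell was Rbf itself. That list had adjusted p = 0.00278 by camera in limma, and adjusted p = 0.822 with an estimated correlation.

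Of 30 measured Polycomb and Trithorax genes, 8 rose and 0 fell in rbf1 mutant discs (11 and 0 adjusted over the list alone), with a median of 0.093. Camera in limma gave adjusted p = 0.000238, and adjusted p = 0.612 with an estimated correlation. esc rose by 0.78 (SE 0.102), Su(z)12 by 0.48 (SE 0.044) and Jarid2 by 0.43 (SE 0.046), all of Polycomb repressive complex 2, and Sfmbt rose by 0.29. Without rbf1 3, 5 of these genes rose. Of 54 other regulators known as Polycomb targets, 6 rose and 0 fell (6 and 1 adjusted over the list alone), where 10.2% of all genes passed. Their median was 0.037, and the list did not pass by camera (adjusted p = 0.543). mid rose by 0.56 and tsh by 0.29. Without rbf1 1 or rbf1 2, 3 of these genes rose. None of the 4 measured Hox genes passed, with Antp at 0.22, pb at -0.16, Scr at -0.14 and Dfd at 0.029, while lab, Ubx, abd-A and Abd-B were not measured. Of 35 germline genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a list adjusted p of 0.0867. Those with the smallest adjusted p act in the piRNA pathway: spn-E rose by 1.22 (SE 0.067), tej by 1.06 (SE 0.132) and vret by 0.42 (SE 0.069). Without control 2, control 3 or rbf1 2, 3 germline genes rose.

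Of 36 photoreceptor differentiation genes in rbf1 mutant discs, 2 rose and 1 fell, over all genes and adjusted over the list alone, and the list had a median of 0.0013 (adjusted p = 0.806). Appl rose by 0.41, B-H1 rose by 0.28 and nrv3 fell by 0.34. B-H1 lost its call without control 2, control 3, rbf1 1 or rbf1 2 (adjusted p up to 0.0886). Of 21 furrow and early neurogenesis genes, 0 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.442). E(spl)m4-BFM fell by 0.38 (SE 0.048) and Brd stood at -0.35, while the proneural gene ato stood at -0.31 without passing. The Brd call was lost without any 1 array but control 3 (adjusted p up to 0.0907). Of 10 retinal determination genes, tsh rose and toy fell by 0.24, also adjusted over the list alone (list adjusted p = 0.581). toy lost its call without rbf1 2 (adjusted p = 0.0549) and with the mean of its probe sets (adjusted p = 0.155). Among 10 Hippo pathway outputs CycE alone rose, by 0.79 (SE 0.146), also adjusted over the list alone (list adjusted p = 0.446). Of 11 JAK/STAT genes, 0 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.993).

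Of 35 respiratory chain genes in rbf1 mutant discs, 0 rose and 2 fell (0 and 1 adjusted over the list alone), with a median of -0.065. UQCR-Q fell by 0.22, and Scsalpha1 fell by 0.15, a call lost without any 1 of the 6 arrays (adjusted p up to 0.125). Camera gave the respiratory chain adjusted p = 0.00217 in limma, and adjusted p = 0.822 with an estimated correlation. Its median was -0.042 without control 2, where the list no longer passed (adjusted p = 0.0809), and -0.12 without control 3. Of 25 apoptosis and stress genes, 3 rose and 1 fell (4 and 2 adjusted over the list alone), with a list adjusted p of 0.581. Corp, a p53 target, rose by 1.09 (SE 0.187) and Irbp18 fell by 0.26. Irbp at 0.33 and wgn at 0.28 passed with all arrays, and 1 list member rose without control 1, rbf1 1, rbf1 2 or rbf1 3 and with the glue gene covariate. Of 23 antimicrobial and immune genes, Dif rose by 0.30 and Def and PGRP-SC2 fell, at -1.03 and -0.23 (2 and 3 adjusted over the list alone, list adjusted p = 0.581). Dif lost its call without any 1 array but rbf1 2, Def without control 2 or any 1 rbf1 array and PGRP-SC2 without any 1 of the 6 (adjusted p up to 0.0984, 0.12 and 0.126). Of 33 detoxification genes, GstE5 rose by 0.52 and GstD2 and Ugt302C1 fell, at -0.73 and -0.32 (2 and 3 adjusted over the list alone, list adjusted p = 0.446).

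Of 30 ecdysone response genes, 0 rose and 1 fell, Edg78E at -0.26 (0 and 0 adjusted over the list alone, list adjusted p = 0.750), a call lost without any 1 of the 6 arrays (adjusted p up to 0.114). Of 27 genes in the ribosome biogenesis list, Rrp1 alone rose, by 0.45, also adjusted over the list alone (list adjusted p = 0.232). In the fly this symbol names a DNA repair endonuclease gene, so the list shows no rise of a ribosome biogenesis gene. Of 6 heat shock genes, 0 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.464). The 5 measured strain markers gave 0 and 0 as well, also adjusted over the list alone (adjusted p = 0.648).

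Markers of other tissues were measured on the same arrays. The mean of 6 salivary glue genes was 6.52, 13.10 and 13.03 in control 1 to 3 and 6.40, 11.75 and 7.11 in the rbf1 arrays, so it varied within both groups. Of 16 salivary gland genes, 1 rose, sens-2 by 0.35, and 0 fell, also adjusted over the list alone, with Sgs1 at -2.70 and Sgs3 at -2.59 not passing (list adjusted p = 0.598). Of 19 tracheal, cuticle and epidermis genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone), with a median of -0.16. They were dyl, which shapes apical extensions, at -0.82, the chitin synthase gene kkv at -0.27, Lcp65Ae at -0.28, knk at -0.25 and Twdlbeta at -0.86. For cuticle genes adjusted p was 0.00411 by camera in limma, adjusted p = 0.256 with an estimated correlation, and adjusted p = 0.0701 among genes above the median level. Without control 2, 3 of its genes fell, and 2 fell without rbf1 1, rbf1 2 or rbf1 3. With the glue gene covariate 2 fell and the median was -0.11 (list adjusted p = 0.0106). Of 15 fat body genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone), with a median of -0.45 (list adjusted p = 0.232). Yp2 was higher by 0.34, and Obp99b, fat-spondin and Cyp4e2 stood at -1.68, -0.86 and -0.56. Without rbf1 1, 0 of these fell, and 1 fell without rbf1 2 or with the glue gene covariate. Yp2 lost its call without control 2, control 3, rbf1 1 or rbf1 3 (adjusted p up to 0.12). Of 19 haemocyte genes, 0 rose and 3 fell, also adjusted over the list alone, namely NimC2 at -1.08 and the prophenoloxidase genes PPO1 at -1.25 and PPO2 at -1.10 (list adjusted p = 0.0867). Without control 2, rbf1 1 or rbf1 2, or with the replicate number as a block, 1 haemocyte gene fell.

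Of 21 glia genes, repo, nrv2 and htl rose by 0.52, 0.38 and 0.32 and 0 fell, also adjusted over the list alone (list adjusted p = 0.581). Of 33 brain and neuroblast genes, sr rose by 0.49 and Rdl fell by 0.88, also adjusted over the list alone, with a median of 0.030 and a mean of -0.020 (list adjusted p = 0.665). Of 23 muscle genes, twi rose by 0.52 and Mlp60A and TpnC73F fell, at -0.68 and -0.32, also adjusted over the list alone (list adjusted p = 0.598). Of 26 genes of other discs and the antenna, bab1 and vg rose by 0.64 and 0.41 and dan fell by 0.23, also adjusted over the list alone (list adjusted p = 0.750). Of 24 adult testis genes, topi and tomb rose by 0.76 and 0.51 and Mst77F fell by 0.25, also adjusted over the list alone (list adjusted p = 0.993). No member of the male dosage compensation RNA list was among the genes tested. For the glia, JAK/STAT, other disc, testis and photoreceptor lists the sign of the median, the mean or the camera direction differed from the others. With 1 array left out, the calls of sr (without control 2, control 3, rbf1 1 or rbf1 2, adjusted p up to 0.0752), twi (all but control 1, 0.106), Mlp60A (control 1 or rbf1 2, 0.0572) and TpnC73F (all but control 3, 0.0755) were lost. The mean of the Mlp60A probe sets was -0.26. Also lost were the calls of vg (all but control 3, 0.102), dan (all but control 3, 0.114), topi (rbf1 2, 0.0518) and Mst77F (all but rbf1 1, 0.134).

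In discs overexpressing PSC, fewer genes changed and more of them fell. The largest change was a fall of Cyp6a17, a cytochrome P450 gene, by 5.07 (SE 0.125), from 9.14 ± 0.15 in control discs to 4.07 ± 0.11 (SD, n = 3). Gyc89Da, which encodes an atypical soluble guanylyl cyclase, rose by 3.61 (SE 0.127), and the ionotropic receptor gene Ir76a rose by 3.06 (SE 0.084). For these genes too, an effect of PSC and a difference between stocks cannot be told apart. Of 19 cuticle and 33 detoxification genes 5 and 7 fell, and neither list passed camera with an estimated correlation (adjusted p = 0.0623 and 0.365). Of the 43 replication genes 1 passed, Orc4, higher by 0.32.

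Across the 11983 genes tested with limma, 455 passed in PSC overexpression against control, 170 higher and 285 lower. Of these, 24 were at least 2-fold higher and 39 at least 2-fold lower, and 1979 genes had an unadjusted p under 0.05. The groups separated fully for 21.7% of genes, where chance gives 10%. The count was 277 without control 1, 289 without control 2, 272 without PSC 1 and 250 without PSC 2. It was 275 when only the 6 arrays compared were fitted, and 37 with an unmoderated test of those arrays.

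CG3588 rose by 4.28 (SE 0.158), or 19.4-fold, on its brightest probe set, with the other at 0.22 and their mean at 2.25. Rises followed in CG14419 by 2.64, CG17109 by 2.52 and Gr64a by 2.21. swi2 rose by 2.18 and raskol, a Ras GTPase activating protein gene, by 1.85 (SE 0.057). The fall of Cyp6a17 was 33.6-fold (limma adjusted p = 4.59e-07), to below the most common low value of the genes tested. Falls followed in CG9150 at -3.33 (SE 0.127), CG8850 at -3.13 (SE 0.106), CG4757 at -2.66, CG4962 at -2.59, CG13032 at -2.20 and Mal-A1 at -2.15. CG32055 fell by 1.95, with Osi6 at -1.73, the activin-like ligand gene daw at -1.63, Cyp6d2 at -1.62 and the serpin gene Spn42De at -1.53. Mal-A1 lost its call without control 1 (limma adjusted p = 0.0530) and CG32055 without PSC 1, PSC 2 or PSC 3 (limma adjusted p up to 0.0757).

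Of the 19 tracheal, cuticle and epidermis genes, 0 rose and 5 fell in PSC discs (0 and 8 adjusted over the list alone), with a median of -0.25. The chitin-binding protein gene obst-A fell by 0.77 (SE 0.050), with dyl at -0.96, Twdlbeta at -1.01, dy at -0.59 and obst-B at -0.36. Adjusted p for the list was 1.74e-05 by camera in limma, and adjusted p = 0.0623 with an estimated correlation. Its median was -0.13 without control 3 or without PSC 2. Without control 1 or control 3, or with the replicate number as a block, 3 of its genes fell, and 2 fell without control 2, PSC 1, PSC 2 or PSC 3. Of the 33 detoxification genes, 2 rose and 7 fell (2 and 10 adjusted over the list alone), with a median of -0.15. Besides Cyp6a17, GstE5 fell by 0.70 and Ugt302C1 stood at -0.53, and the rises were GstD9 by 0.98 and Cyp4p1 by 0.45. For detoxification adjusted p was 0.0011 by camera in limma, adjusted p = 0.365 with an estimated correlation, and adjusted p = 0.466 among genes above the median level. Without control 1, control 2, PSC 1 or PSC 3, 4 of its genes fell, and 3 fell without PSC 2.

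The list of Polycomb target genes passed in PSC discs by camera in limma with the preset correlation (adjusted p = 0.0108), but not with an estimated one (adjusted p = 0.466) or by fry (adjusted p = 0.114). Of the 54 regulators outside the Hox genes, 0 rose and 5 fell, also adjusted over the list alone, with a median of -0.064, where 3.80% of all genes passed. They were tio at -0.57 (SE 0.087), vg at -0.59, Dr at -0.60, chinmo at -0.79 and NK7.1 at -0.26, all transcription factor genes. Without control 1, control 3 or PSC 1, 2 of these genes fell, 1 fell without PSC 2 and 3 fell without PSC 3. The list no longer passed without control 3 (median -0.061, adjusted p = 0.0811) or PSC 2 (median -0.031, adjusted p = 0.146), and its median was -0.038 without control 1. None of the 4 measured Hox genes passed, with pb and Scr at -0.25, Dfd at -0.19 and Antp at -0.15. The listed Hox genes lab, Ubx, abd-A and Abd-B were not among the genes tested. The Antp probe set used had a mean of 5.25, not far above the most common low value of 4.19, so a fall there would be compressed. These values therefore do not decide whether PSC lowers Hox genes. Of 30 Polycomb and Trithorax genes Psc alone rose (2 and 0 adjusted over the list alone, list adjusted p = 0.0752, and 0.211 without Psc).

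Of the 43 replication genes, 1 rose and 0 fell in PSC discs (0 and 0 adjusted over the list alone), with a median of 0.12. Orc4 lost its call without any 1 of the 6 arrays (adjusted p up to 0.134). Their list had adjusted p = 0.00157 by camera in limma, and adjusted p = 0.728 with an estimated correlation. It did not pass without control 3 (median 0.052, adjusted p = 0.229) or PSC 2 (median 0.049, adjusted p = 0.208), and its median was 0.19 without PSC 3. Of 41 mitosis genes, glu rose by 0.49 and Cap-D3, also of condensin, by 0.38 (4 and 0 adjusted over the list alone), with a median of 0.070. Cap-D3 lost its call without any 1 array but PSC 1 (adjusted p up to 0.0881). Mitosis genes had adjusted p = 0.00612 by camera in limma, and adjusted p = 0.728 with an estimated correlation. It did not pass without control 3 (median 0.019, adjusted p = 0.229) or PSC 2 (median 0.021, adjusted p = 0.146), and its median was 0.13 without control 2 or PSC 3. Of 5 strain markers, ry fell by 0.46 and y fell by 0.31, also adjusted over the list alone, with cn at -0.12, sc at -0.059 and Cyp6g1 at -0.016. That list had a median of -0.12 and adjusted p = 0.0162 by camera in limma, and adjusted p = 0.365 with an estimated correlation. It did not pass without control 3 (median -0.099, adjusted p = 0.0734) or PSC 2 (median -0.068, adjusted p = 0.128), and its median was -0.064 without control 1 and -0.19 without control 2. The y call was lost without PSC 1, PSC 2 or PSC 3 (adjusted p up to 0.0602).

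By camera in limma no other list passed in PSC discs, while by fry the JAK/STAT list passed (adjusted p = 0.00278). The Polycomb and Trithorax list passed by fry with Psc itself as a member (adjusted p = 0.00996) and not without it (0.335). Without Rbf the list of RB, E2F and DREAM proteins passed by camera with the preset correlation (0.0425). With Rbf that list had adjusted p = 0.728 by camera with an estimated correlation, a setting not run without Rbf. Lists without both genes were chosen after the data were seen. By camera, lists with 0 genes rising and 0 falling, also adjusted over the list alone, were the 17 RB, E2F and DREAM proteins (adjusted p = 0.0508), the 35 germline genes (0.745), the 10 Hippo outputs (0.573) and the 21 furrow genes (0.370). The 27 ribosome biogenesis genes (0.0611), the 35 respiratory chain genes (0.115), the 16 salivary gland genes (0.875), the 19 haemocyte genes (0.798) and the 24 testis genes (0.798) likewise gave 0 and 0. The 36 photoreceptor genes gave 0 and 0 over all genes, and 2 and 5 adjusted over the list alone (adjusted p = 0.622). The 6 heat shock genes gave 0 and 0, and 0 and 2 adjusted over the list alone (adjusted p = 0.123). The haemocyte list had a median of -0.021, a negative camera direction and a mean of 0.061. The glue gene mean was 9.53, 10.08 and 12.24 in PSC 1 to 3.

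Single members passed in several of the remaining lists. chinmo alone fell among 11 JAK/STAT genes and tio among 10 retinal determination genes (0 and 1, and 0 and 2, adjusted over the list alone, list adjusted p = 0.0784 and 0.280). Irbp18 fell by 0.29 among 25 apoptosis genes and MsrA fell by 0.46 among 30 ecdysone response genes, each also adjusted over the list alone (list adjusted p = 0.115 and 0.0892). Among 23 immune genes Tep4 and Listericin fell, at -0.66 and -0.95, also adjusted over the list alone (list adjusted p = 0.564). Strn-Mlck fell by 0.55 among 23 muscle genes and vg and ana, at -0.59 and -0.47, fell among 26 genes of other discs, each also adjusted over the list alone (list adjusted p = 0.141 and 0.187). Cyp4e2 fell by 0.60 among 15 fat body genes (1 and 2 adjusted over the list alone, list adjusted p = 0.798). Among 21 glia genes repo rose by 0.23 and Eaat2 fell by 0.43 (3 and 2 adjusted over the list alone, list adjusted p = 0.798). Among 33 brain genes mira rose by 0.70 and Rdl and ase fell, at -0.55 and -0.95 (3 and 2 adjusted over the list alone, list adjusted p = 0.798). Of these, tio, Irbp18, Tep4 and Rdl passed with each of the 6 arrays left out. repo lost its call without any 1 array, and Listericin (all but PSC 3, adjusted p up to 0.109), Eaat2 (all but PSC 1, 0.138), mira (all but control 3, 0.152) and ase (all but control 2, 0.0881) without nearly any. chinmo (control 2, control 3, PSC 1 or PSC 2), MsrA (control 1, control 2, PSC 2 or PSC 3), Cyp4e2 (any control or PSC 1), ana (control 1, control 3, PSC 2 or PSC 3), vg (control 1, PSC 1 or PSC 2) and Strn-Mlck (control 1 or PSC 2) lost theirs with adjusted p up to 0.0722, 0.0706, 0.0664, 0.0631, 0.0628 and 0.0526. The Strn-Mlck call was also lost with the mean of its probe sets (-0.15, adjusted p = 0.180).

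**Figure D2:**
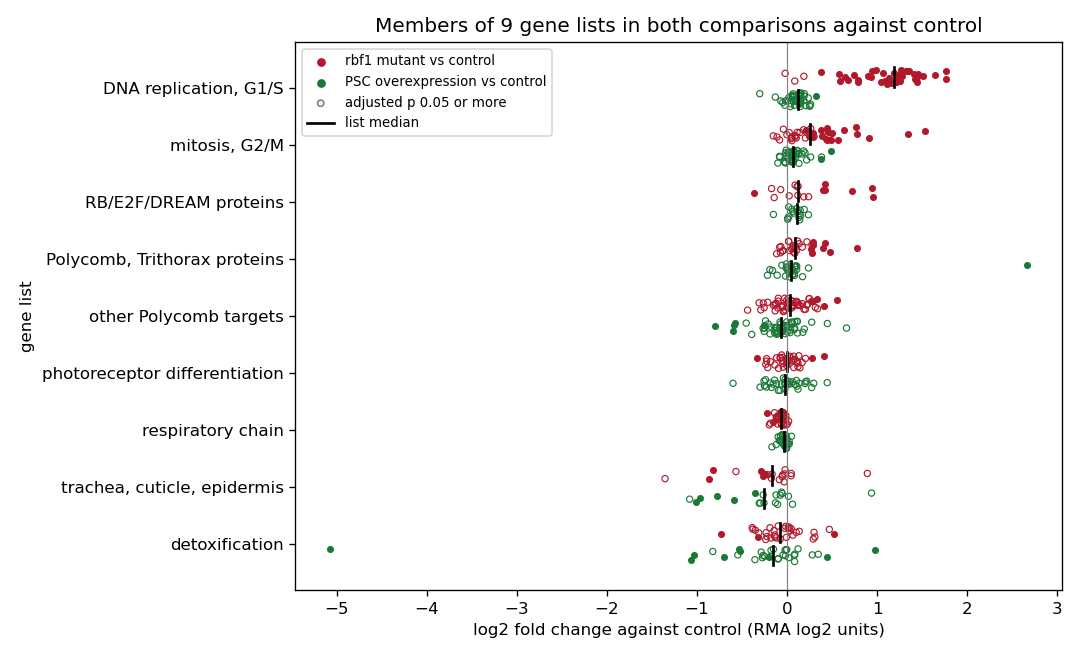
Log2 fold change against control of each measured member of 9 gene lists, for the rbf1 mutant (red) and PSC overexpression (green), with filled points for a limma adjusted p under 0.05 over all genes, open points for the rest and black bars at list medians. The replication list has its median at 1.19 in the rbf1 mutant and at 0.12 in PSC discs.

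The difference between both effects was tested directly as rbf1 mutant against PSC overexpression. The replication genes again led it, with 40 of 43 higher in rbf1 mutant discs and 0 lower, also adjusted over the list alone, and a median of 1.04. Cyp6a17 was 5.54 higher (SE 0.125) and CG9150 3.85 higher (SE 0.127) in rbf1 mutant discs, followed by sut2 at 3.27 and UK114 at 2.97. inaE was lower in the rbf1 mutant, at -4.23 (SE 0.087) and at -1.10 with the mean of its probe sets, and Gyc89Da, CG6034 and Ir76a followed, 14.4-fold, 9.26-fold and 7.98-fold lower. With limma, 1266 genes passed, 828 higher and 438 lower in the rbf1 mutant, of which 109 and 51 at least 2-fold, and 2767 had an unadjusted p under 0.05. The groups separated fully for 30.5% of genes, where chance gives 10%. With arrays centred on their medians the split was 580 higher and 748 lower, and the count was 843 without PSC 1 and 843 without rbf1 2.

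Of the 28 lists tested in this comparison, 5 passed by camera in limma and 0 with an estimated correlation. The replication list had adjusted p = 1.09e-43, and adjusted p = 0.545 with an estimated correlation. Of 41 mitosis genes, 13 were higher and 1 lower, Cap-D3 at -0.46 (19 and 2 adjusted over the list alone, list adjusted p = 1.14e-06, and adjusted p = 0.662 with an estimated correlation). Of 35 germline genes, 5 were higher and bam lower at -0.49 (7 and 1 adjusted over the list alone, list adjusted p = 0.0221, and adjusted p = 0.545 with an estimated correlation). Among the 5, mael stood at 0.86, spn-E at 1.09 and tej at 0.94. Of 54 other Polycomb target regulators, 14 were higher and 2 lower in the rbf1 mutant, with a median of 0.066 (15 and 3 adjusted over the list alone, list adjusted p = 0.0221, and adjusted p = 0.545 with an estimated correlation). Those higher included chinmo at 1.04, Dr at 0.91 and NK7.1 at 0.52, and those lower were dac at -0.49 and C15 at -0.31. Of 30 Polycomb and Trithorax genes, 6 were higher, Su(z)12 at 0.40 and esc at 0.61 among them, and Psc was lower at -2.53 (9 and 2 adjusted over the list alone, list adjusted p = 0.0437, and adjusted p = 0.662 with an estimated correlation).

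Some genes passed in both comparisons against control. CG3588, CG14419, Gr64a and raskol rose in both, raskol by 1.72 in the rbf1 mutant and by 1.85 in PSC discs on its brightest probe set. Another raskol probe set passed in the other direction, at -0.39 and -0.42 (limma adjusted p = 0.00964 and 0.0136), a further one stood at 0.11 and 0.081, and the mean of all was 0.48 and 0.50. CG8850, CG13032, CG4962 and Mal-A1 fell in both, CG4962 with differences of -2.16 and -2.59. In all, 65 genes were higher in both and 111 lower in both, where lists drawn independently would share 10.7 and 11.2. In 50 simulations of unchanged groups against the same control arrays the highest count was 0 in each direction, which is the number with no effect in either group and no reference for lists that hold real effects. A further 26 genes passed in opposite directions, against 24.6 for independent lists. CG9150 (0.52 and -3.33), GstE5 (0.52 and -0.70), CG11158 (0.85 and -0.70) and Set8 (0.81 and -0.48), which encodes a histone H4 methyltransferase, were higher in the rbf1 mutant and lower in PSC discs. aay (-0.48 and 0.68), CG18765 (-0.51 and 0.45), Cyp4p2 (-0.62 and 0.40) and CG7860 (-0.48 and 0.39) went the other way. Of these 8 opposite genes, GstE5, Cyp4p2 and CG7860 kept both calls with each array left out, and the rbf1 call of CG9150 was lost without any 1 of the 6 arrays (limma adjusted p up to 0.117). aay lost its rbf1 call without control 1, control 3, rbf1 1 or rbf1 2 and its PSC call without control 1, control 2, PSC 1 or PSC 2 (limma adjusted p up to 0.0996 and 0.0633). In PSC discs, the CG11158 call was lost without any 1 control or PSC 1, that of CG18765 without control 1, control 2, PSC 1 or PSC 3, and that of Set8 without control 1, control 2, PSC 1 or PSC 2 (limma adjusted p up to 0.113, 0.0586 and 0.0767).

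Of the 176 genes that passed in one direction in both comparisons, 37 also differed between rbf1 mutant and PSC discs and 139 did not pass that test. Their number was 112 without control 1, 98 without PSC 1, 103 without PSC 2, 117 without rbf1 2 and 116 without rbf1 3. Across all genes the correlation of both sets of fold changes was 0.503, and 0.502 in the simulations with no effect. Genes are not independent replicates. The covariance was 0.0438 against a simulated 0.0230, a difference of 0.0208. The fold changes had the same sign for 65.4% of genes, and for 66.7% in the simulations. Since 3 control arrays cannot be split into parts of at least 2 each, part of the excess of shared calls may come from the shared controls.

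**Figure D3:**
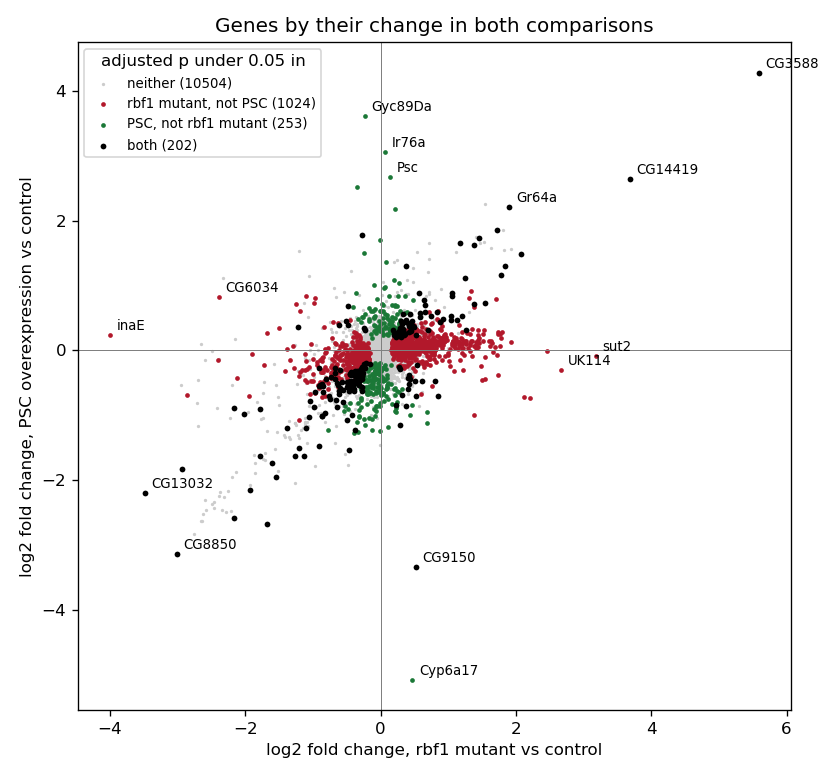
Log2 fold change against control of each of the 11983 genes in the rbf1 mutant (x axis) and in PSC overexpression (y axis), coloured by the comparison in which the limma adjusted p was under 0.05. Genes called in both (202, black) lie mainly along the diagonal, while Psc, Gyc89Da and Cyp6a17 lie near the vertical axis and inaE, sut2 and UK114 near the horizontal one.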

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

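The probe sets without a single gene in the annotation entered no comparison above, and some of them changed. Of 5122 such probe sets, 206 passed in rbf1 mutant against control (123 higher, 83 lower) and 72 in PSC overexpression against control (34 higher, 38 lower) by limma. In the rbf1 mutant 1637602_at stood at -4.38 and 1631321_s_at at 4.34, 1637046_at at 4.004 and 1630585_s_at at 3.16 on the log2 scale. In PSC discs 1624819_s_at stood at -3.52, 1624543_s_at at 2.84, 1631549_s_at at -2.44 and 1627266_at at 2.01. They are listed here because this signal lies in data that the comparisons do not use.

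Of the tests below, those of the share of cycling cells, brain tissue, shared control noise, RNA integrity, ring gland tissue and a single deviating control array were chosen after the results they bear on were seen. The ecdysteroid synthesis list was also written after. The glue gene covariate of the salivary gland test was added after the data were seen, and what the test would show was written before its result.

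By their median, replication genes rose far more in the rbf1 mutant than the other cell cycle lists. A larger share of cycling cells with the same mix of phases would raise mitosis genes as much if both lists depended on it alike. The median of 43 replication genes exceeded that of 41 mitosis genes (1.19 against 0.26). Taken per array, since genes of one list correlate, the replication median minus the mitosis median was 0.88 to 0.95 in the rbf1 arrays and -0.061 to 0.025 in the control arrays, a difference of 0.92 with an SD of 0.042 within groups. Brain tissue with cycling neuroblasts left on the discs would raise its markers too, yet the 33 brain and neuroblast genes had a median of 0.030 with an interquartile range of 0.31, and the 9 of them above the median level of all genes had 0.096 with 0.24. The mitosis genes spread widely (quartiles 0.091 and 0.45), and how far each depends on cycling cells was not tested. The gap between the lists therefore cannot decide on a larger share of cycling cells, which stays open. The brain values argue against brain tissue as the whole cause. A changed mix of phases, with more cells in or near S phase, remains open. An effect of the rbf1 genotype also remains open and was not tested apart from the groups.

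Genes changed the same way in both comparisons numbered 176. When 1 control array served one comparison and the other 2 served the other, in all 6 ways, same-direction calls numbered 38 to 93 and opposite ones 4 to 21. The former were 6.27 to 13.8 times the number for independent lists, with the lone array assumed to vary like the others. Over all genes the covariance of both sets of fold changes was then -0.0114 to 0.0235, against 0.0438 with shared controls, so the agreement across all genes owes much to them. For the calls, this count argues against noise of the shared control arrays as the whole cause, and part of the overlap may still come from it. With the glue gene covariate 116 of the 176 stayed called in both, which argues against salivary gland tissue as the whole cause. The glue gene mean itself overlapped between the groups, at 6.52 to 13.10 in the control arrays and 6.40 to 12.24 in the altered arrays. The mean of 15 ecdysteroid synthesis genes did not, at 7.99 to 8.54 and 8.73 to 9.65, and one of them, dib, is among the 176. Whether ring gland tissue adds to the overlap was not tested. Lower RNA integrity in the altered groups stays open. The 3' minus 5' difference of Act5C was 0.78 to 0.80 in the control arrays and 0.85 to 1.10 in the altered arrays, with no overlap, while those of Gapdh and eIF4A overlapped. The mean over these control genes was higher by 0.016 in the altered arrays, within the SD of 0.061 inside groups. A different genetic background of the control stock would place such genes side by side only where the stocks differ over longer stretches of the genome. Scattered differences would leave no such pairs, so a low count could not exclude them. There were 6 neighbouring pairs, where random lists of the same size gave a median of 3 and a 95th percentile of 6. The other called genes had 14 pairs in PSC discs, against 6.498 for independent placement, and 111 against 91.3 in the rbf1 mutant, so that an excess is not particular to the same-direction genes. One pair was Gr64a and Gr64f, and 5 of the 6 pairs moved the same way, so that a background difference cannot be told apart from the groups by this count. A response common to both genotypes may also contribute and stays untested, since stock and culture go with the group.

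Genes of ecdysteroid synthesis in the prothoracic gland had higher values in both altered groups than in the control. Of 15 genes, 15 had positive fold changes in the rbf1 mutant and 13 in PSC discs, with medians of 0.72 and 0.89, dib and ouib called in the first and dib in the second (11 and 0 adjusted over the list alone in each). Whether more ring gland tissue was left on the altered discs stays open. Some of these transcripts stood high in every preparation, control included. spok ran from 9.78 to 11.49 in the control arrays and from 11.41 to 12.85 in the altered arrays, while Cyp6t3 stayed at 4.50 to 4.71. The residuals of the 15 genes over the 9 arrays correlated with each other at a mean of 0.38. That is above the 99th percentile of matched random lists (0.24, with a highest of 0.44). Genes regulated together correlate as well, up to 0.685 in the replication list, so this value does not separate tissue from regulation. A single deviating control array does not account for it, since the median stayed at 0.67 or above in the rbf1 mutant and 0.79 or above in PSC discs with each control left out. A difference in regulation or larval stage between genotypes remains open.

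The arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For rbf1 mutant against control 1 of the 10 splits, the real one, gave 1226 genes and the highest other gave 1. For PSC overexpression against control the real split gave 455 and the highest other 1, and for rbf1 mutant against PSC overexpression the real split gave 1266 and the highest other 0. Every other split mixes both groups on each side, so that any group difference widens the spread and lowers its count. Only the rank of the real split is informative, and the low counts do not measure false calls.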

How the results depend on the processing

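Centring the arrays on their medians turned the majority of calls from higher to lower in the rbf1 mutant, at 559 higher and 603 lower against control and 580 and 748 against PSC overexpression. With the mean of all probe sets per gene 4, 2 and 2 called genes had the other sign, and 0 in the other fits of the same 11983 genes. Signs were not counted over single probe sets, where raskol had sets that passed in both directions. Counts of called genes (rbf1 mutant against control, PSC overexpression against control, rbf1 mutant against PSC overexpression) were 164, 63 and 160 with a 2-fold minimum, 599, 168 and 632 at a threshold of 0.01, and 481, 37 and 608 with an unmoderated test. The first pair of settings is stricter by construction. The unmoderated test also used only the 6 arrays compared, so lost moderation and lost arrays are not told apart in its counts. A 2-fold minimum left 26 same-direction genes in both. PSC against control gave 275 when only its 6 arrays were fitted, which leaves fewer degrees of freedom. Array weights gave 1356, 651 and 1876, and the glue gene covariate, chosen after the data were seen, gave 882, 381 and 967. With 1 array left out the counts ran from 787 to 969, 250 to 385 and 843 to 986, and the shared calls from 98 to 148.

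With an estimated correlation none of the 12 list calls against control passed. Their medians are by construction unchanged, in the rbf1 mutant 1.19 for replication, 0.26 for mitosis, 0.12 for RB/E2F/DREAM, 0.093 for Polycomb proteins, -0.065 for the respiratory chain and -0.16 for cuticle, and in PSC discs 0.12, 0.070, -0.064, -0.15, -0.25 and -0.12 for replication, mitosis, Polycomb targets, detoxification, cuticle and strain markers. By fry the respiratory chain (-0.065, adjusted p = 0.280), and in PSC discs replication (0.12, adjusted p = 0.442), mitosis (0.070, adjusted p = 0.390) and Polycomb targets (-0.064, adjusted p = 0.114) did not pass. It passed 5 further lists, in the rbf1 mutant germline (0.040, adjusted p = 0.0102), Hippo (0.039, adjusted p = 0.0203) and glia (-0.0023, adjusted p = 0.0336), and in PSC discs JAK/STAT (-0.058, adjusted p = 0.00278) and Polycomb proteins (0.041, adjusted p = 0.00996), the last not without Psc (0.035, adjusted p = 0.335). Without Rbf and Psc in the lists, chosen after the data were seen, camera lost 0 list calls, and by fry Polycomb targets had adjusted p = 0.137. Among genes above the median level, cuticle in the rbf1 mutant (-0.068, adjusted p = 0.0701) and detoxification in PSC discs (-0.094, adjusted p = 0.466) did not pass, where fewer genes were tested. List medians with 1 array left out ran from 1.09 to 1.26 (replication), 0.21 to 0.29 (mitosis), 0.11 to 0.15 (RB/E2F/DREAM), 0.079 to 0.12 (Polycomb proteins), -0.12 to -0.042 (respiratory chain) and -0.21 to -0.11 (cuticle) in the rbf1 mutant. In PSC discs they ran from 0.049 to 0.19 (replication), 0.019 to 0.13 (mitosis), -0.073 to -0.031 (Polycomb targets), -0.15 to -0.11 (detoxification), -0.30 to -0.13 (cuticle) and -0.19 to -0.064 (strain markers). The cause of calls lost with an array left out was not tested. Over all alternatives 987 list values kept their side of the threshold, 44 gained and 31 lost a call, and for named genes the numbers were 3864, 61 and 325.

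With the replicate number as a block the counts were 1306, 426 and 1315, of which 1100, 355 and 1114 were shared with the unblocked calls. Of the 12 list calls against control, 0 were lost. The numbers are not known to pair the arrays, since 4 of 9 same-number pairs correlated above 0.1 (-0.44 to 0.59) and in 7 of 18 cases an array correlated best with its own number. On the other hand, the mean of the poly-A spikes was lowest in array 1 and highest in array 3 of each group. Whether the arrays were processed by number therefore stays open. Signal near background limits the fold changes of dim genes, which end near 4.19.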

Other observations

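The lists in this part were written after the largest changes had been seen. Of 43 measured DNA repair and checkpoint genes, 19 rose and 1 fell in rbf1 mutant discs, Top3beta (23 and 3 adjusted over the list alone), with a median of 0.23, and in PSC discs hay rose and Fancm fell, at -0.66 (2 and 3 adjusted over the list alone). The exonuclease gene WRNexo was higher by 1.74, the helicase gene RecQ4 by 1.73 and timeout by 1.62. Camera in limma gave adjusted p = 3.4e-10 for the rbf1 mutant, and adjusted p = 0.132 with an estimated correlation. In PSC discs the list had adjusted p = 0.668.

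Of 11 measured genes of metal response, 0 rose and 4 fell in rbf1 mutant discs (0 and 5 adjusted over the list alone), namely the metallothionein genes MtnB at -2.12 and MtnD at -1.41, the copper transporter gene Ctr1A at -0.40 and Zip71B at -0.25. The list had adjusted p = 0.0118 by camera in limma, and adjusted p = 0.132 with an estimated correlation. In PSC discs 0 rose and 0 fell, with MtnA at 0.62 not passing. Of 29 digestive enzyme and gut genes, Mal-B1 rose and Mal-A1 fell in both comparisons, and Mal-B2 fell in PSC discs, at -0.85, with the same counts adjusted over the list alone (list adjusted p = 0.238 and 0.927).

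The ecdysteroid synthesis list had adjusted p = 9.42e-06 in the rbf1 mutant and 2.91e-06 in PSC discs by camera in limma, and adjusted p = 0.132 and 0.317 with an estimated correlation. Between rbf1 mutant and PSC discs 0 of its 15 genes passed, and the median was -0.078. Its mean log2 value was 8.21, 8.54 and 7.99 in control 1 to 3, 8.73, 9.65 and 9.21 in the PSC arrays, and 9.15, 8.83 and 9.44 in the rbf1 arrays.

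The mean of the poly-A spike control probe sets was 7.94, 8.16 and 8.40 in control 1 to 3, 8.14, 8.45 and 8.69 in PSC 1 to 3, and 8.09, 8.20 and 8.68 in rbf1 1 to 3. Each altered array lay above the control array of its number. Control 3 had the lowest mean correlation with the other arrays, 0.985.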
